A study of Xenopus laevis with 6 samples.

How the data were processed

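RNA was measured in animal caps of Xenopus laevis, the pluripotent ectoderm cut from the top of the early embryo, at gastrula stage 10.5. The 6 Affymetrix arrays fell into 3 groups of 2: uninjected caps, caps from embryos injected with Mixer, and caps from embryos injected with Sox17beta. Mixer is a homeodomain transcription factor and Sox17beta an HMG-box transcription factor, both known as regulators of endoderm formation. Groups and replicate numbers were taken from the sample labels. The labels name no separate embryo batches or clutches, so the p-values measure only the spread between these samples, which may be technical.

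The values used were the deposited log2 expression values per probe set, summarised with RMA per the submitters' processing notes. RMA subtracts background, brings the arrays to a common distribution and summarises the probes of a probe set. The version, the chip software and whether the 6 arrays were summarised in 1 run are not given in the sources used here. Values ran from 2.24 to 14.07 with 2 decimals, and array medians lay between 6.49 and 6.54, so no further logarithm, background correction or normalization was applied. Differences on this scale can understate changes of probe sets near background. No column of another series was used, and the number of such columns was 0. The number of arrays, 2 per group, limits the precision.

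Of 15611 probe sets, 120 controls were left out and 15491 were tested. Gene names came from the platform's annotation table, in which 9304 of the tested probe sets had 1 gene symbol, 195 had several and 5992 had none. By gene identifier, 9227 matched a reference annotation, which updated 2 symbols, and 290 symbols were placeholders. A probe set with several symbols or none is unnamed here and is described by its values and groups. The endings .L and .S mark the gene copies on the long and short chromosomes of the duplicated genome of this species. No genome coordinates are given, because the values are tied to probe sets and no genome build is named in the sources used here.

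Group means were fitted with lmFit and compared with eBayes in limma 3.58.1 (R 4.3.3). All 6 arrays entered 1 fit with a mean per group and no block, and the 3 comparisons were Mixer against uninjected, Sox17beta against uninjected, and Mixer against Sox17beta. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and the threshold was an adjusted p of 0.05 with no requirement on fold. Errors are standard deviations over the 2 arrays of a group or standard errors from the fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

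The labels give each group replicate numbers 1 and 2, so it was checked whether a number marks arrays that vary together. Deviations from the group means correlated across probe sets at 0.867 between uninjected and Mixer arrays of the same number, at 0.732 between uninjected and Sox17beta, and at 0.776 between Mixer and Sox17beta. Each of the 6 arrays correlated best with an array of its own number. The first principal component held 55.5% of the variance and separated number 1 from number 2, and the second held 26.3% and separated the groups. The pairing comes from the numbers in the labels and was accepted on these correlations before the calls of the 2 fits were compared. A fit with the replicate number as a block, listed as an alternative from the start, is therefore given beside each result whose call or count it changes. The log2 differences are identical with and without the block, and the residual degrees of freedom were 2 with it and 3 without.

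The fits were tested on simulated data for Mixer against uninjected, in 10 draws with 200 of the 15491 probe sets changed. The fit without a block recovered 0.1% of 2-fold and 53.8% of 4-fold changes, and 0% of its calls were false. The fit with the block recovered 99.5% of 2-fold and 100% of 4-fold changes, and 10.3% of its calls were false, above the share that the threshold of 0.05 allows. The list test called the shifted list in 10 of 10 draws and made 0 calls among 3 unshifted lists. In all draws the noise had spreads that the blocked fit had already drawn towards a common value, so recovery may be overstated. Apart from the replicate effect, the noise was independent between probe sets. In the data, the estimated correlation between epidermal genes was 0.425 with the block. The draws therefore do not test how correlation within a list affects its call.

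Before the data were examined, the groups, the comparisons, the tests, the alternatives, 16 gene lists and the rule for named genes were fixed. Per comparison, the rule took the 12 largest rises and 8 largest falls among called probe sets with 1 symbol and groups that did not overlap (8 each way between the injected groups). It added every probe set of the injected genes, up to 4 passing genes of each list or the 2 with the smallest p, at most 2 unnamed probe sets each way, and 8 genes shared by both injected groups each way. Because few probe sets passed without the block, the rule was applied to the fit with the block as well, a choice made after the counts were seen. Where a gene had several probe sets, the 1 with the highest mean over all arrays stood for it in a list and in the rule for named genes, except for the injected genes. The lists covered endoderm regulators, later gut and liver genes, Nodal, Wnt and FGF signalling, organizer, mesoderm, ventral and BMP responsive genes, epidermal ectoderm and neural plate. They also covered adhesion, vegetal and germ plasm RNAs, blood and vascular precursors, stress, loading genes and cell cycle. Lists share genes, so their tests are not independent. Each list was tested with camera at its preset correlation of 0.01, adjusted over the 16 lists per comparison. Camera with an estimated correlation and fry were run as alternatives. The estimate was above the preset for some lists, such as 0.262 for epidermal genes without the block. It was below the preset for others, at 0.00326 for endoderm regulators without the block and -0.0145 for vegetal RNAs with it. The p-values of these 2 lists in Mixer caps rose all the same, so the size of the correlation does not account for that rise.

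Alternatives tried were centring on array medians, quantile normalization, filters on dim probe sets, eBayes with trend and with robust, fits on the 4 arrays compared, the replicate block, and leaving out each array. Leaving out an array of the group outside a comparison keeps the log2 differences of that comparison. It changes only the estimate of the spread and its degrees of freedom, as a fit on the 4 arrays compared does. Stricter thresholds and 1 probe set per gene were also tried. Both injected groups share the uninjected arrays, so overlaps and correlations between them were set beside 100 simulations of unchanged groups. With 2 arrays per group, neither a test for single outlying arrays nor a count over other splits of the samples was made.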

Results

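Expression was measured on 6 arrays of 15491 tested probe sets, with 2 arrays each of uninjected, Mixer-injected and Sox17beta-injected animal caps at stage 10.5. Animal caps form epidermis when left alone, and the design asks which genes change when each of these endoderm regulators is supplied. Array medians were alike, at 6.49 to 6.54 on the log2 scale, and 48.5% to 60.7% of probe sets on each array lay above the highest of that array's 44 controls for absent transcripts. Those controls had medians of 3.73 to 4.06. The highest median and the lowest share were those of Sox17beta replicate 1, where the other arrays had 3.73 to 3.85 and 57.8% to 60.7%. Replicate numbers separated the arrays more than the injections did. Arrays of different groups but the same number correlated at 0.967 to 0.986 across probe sets, and arrays of the same group at 0.958 to 0.971. The 18 hybridization controls, RNAs added at hybridization, were 1.23 (uninjected), 1.67 (Mixer) and 1.23 (Sox17beta) higher on the log2 scale in replicate 1 than in replicate 2.

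**Figure D1:**
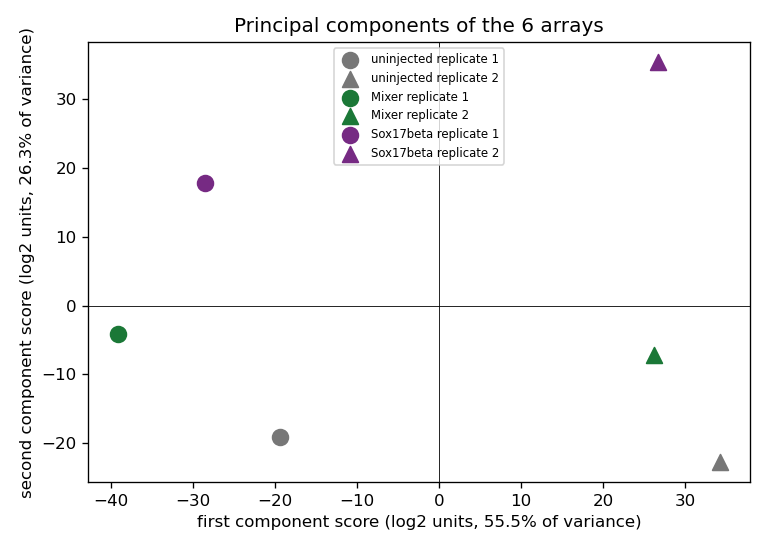
Scores of the 6 arrays on the first and second principal components of the log2 values, with colour for the group and shape for the replicate number. The first component, with 55.5% of the variance, separates replicate 1 from replicate 2, and the second, with 26.3%, runs from uninjected (-19.09 and -22.75) through Mixer (-4.10 and -7.18) to Sox17beta (17.77 and 35.35).

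The injected genes were examined first, since they check the labels. The probe set of mixer.L read 6.5 ± 0.06 (SD, n = 2) in uninjected caps and 14.07 ± 0.01 in Mixer caps, a difference of 7.57 on the log2 scale or 189-fold (limma adjusted p = 0.000934). In Sox17beta caps it read 6.68 ± 0.21, a difference of 0.18 that did not pass (adjusted p = 1). On the Mixer arrays mixer.L gave the highest value of each (14.07 and 14.06), so the small SD and the fold may reflect the top of the range. With quantile normalization the Mixer difference of mixer.L was 7.16. The probe set of mixer.S differed by 0.78 in Mixer caps, with adjusted p = 1 without a block and 0.0302 with the replicate number as a block. Both probe sets of sox17b.1.S rose in Sox17beta caps, the gene-specific one (ending _at) by 6.7 (104-fold, adjusted p = 0.0234) and the one shared by similar transcripts (ending _s_at) by 7.62 (197-fold, adjusted p = 0.00721). They were also higher in Mixer caps, by 2.67 (adjusted p = 0.34, with the block 0.0111) and by 4.14 (adjusted p = 0.0385). Probe sets read injected and embryonic transcripts together, so these values do not separate one from the other. The call of mixer.L ended without uninjected replicate 1 (adjusted p = 0.0528) or replicate 2 (0.0506). Over the 6 single-array omissions, the adjusted p of the shared sox17b.1.S probe set in Mixer caps lay between 0.0753 and 0.592, so each omission ended that call. In Sox17beta caps those of the gene-specific and the shared probe set reached 0.357 and 0.238, and the calls held without Sox17beta replicate 1 for the former and without either Sox17beta array for the latter.

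Mixer against uninjected caps asks which genes Mixer changes in this tissue. In Mixer caps, gata4.L, a zinc-finger transcription factor of endoderm and heart, read 8.73 ± 0.10 (SD, n = 2) against 5.14 ± 0.08 in uninjected caps, a rise of 3.58 ± 0.15 (SE, limma adjusted p = 0.0176). The endoderm regulator sox17a.S rose from 4.31 ± 0.04 to 7.34 ± 0.31, by 3.03 (adjusted p = 0.0405). Without the block 6 probe sets were called, all 6 higher in Mixer caps, and 445 had an unadjusted p under 0.05 where chance gives 775. That fit leaves the variation between replicate numbers in its residual, so a low count there is no sign of a small effect. With the block 1885 had an unadjusted p under 0.05. Besides mixer.L, gata4.L, sox17a.S and the shared sox17b.1.S probe set, these were a pair of unnamed probe sets whose identifiers share a stem, ending _at (3.12, adjusted p = 0.0405) and _x_at (3.06, adjusted p = 0.028). With the replicate number as a block, 203 probe sets were called, 83 higher and 120 lower, of which 110 differed at least 2-fold, 60 higher and 50 lower. At an adjusted p under 0.01 the blocked fit called 18 higher and 4 lower, so the majority direction depended on the threshold.

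The further changes in Mixer caps passed only with the replicate block. The other copy of each endoderm gene rose too, gata4.S by 3.72 (adjusted p = 3e-04) and sox17a.L by 3.17 (0.0134). Rises were also called for itln1.L, a secreted lectin of epidermal mucus, by 3.65 (0.00823), and for the apelin receptor aplnr.L by 2.73 (0.0148). The homeobox gene msx2.L rose by 2.51 (0.00124), the Wnt ligand wnt11b.L by 2.45 (0.0141), cmtm8.L by 2.44 (0.0223; 1.73 and 3.16 in replicates 1 and 2) and pnhd.L by 2.38 (0.00603). Another unnamed probe set was 3.14 higher (0.0464; 2.05 in replicate 1 and 4.23 in replicate 2). The largest fall of a named gene was that of kctd15.L, at -2.28 (0.0262). The glucose transporter slc2a2.L fell by 1.59, the amino acid transporter slc38a2.L by 1.58, the arginine synthesis enzyme asl.L by 1.55 and the polyamine acetyltransferase sat1.L by 1.48, with adjusted p from 0.0111 (sat1.L) to 0.0293 (slc2a2.L). The ectodermal homeobox gene dlx5.L fell by 1.49 (0.0203), the transcription factor sox18.S by 1.46 (0.0203) and bambi.L, a decoy receptor that dampens BMP signalling, by 1.35 (0.0218). The largest falls of unnamed probe sets were -1.9 (0.0203) and -1.66 (0.00576).

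Of 17 measured endoderm regulators, 3 rose and 0 fell in Mixer caps without the block (7 and 1 adjusted over the list alone), and 6 rose and 1 fell with it (11 and 2 adjusted over the list alone). The list's median difference was 0.57 (camera adjusted p = 1.04e-18, adjusted p = 0.0381 with an estimated correlation). With the block the latter became adjusted p = 0.378 with an estimated correlation. Besides the genes above, foxa1.S, a forkhead factor of endoderm, rose by 1.68 and cer1.S, a secreted antagonist of Nodal, BMP and Wnt ligands, by 1.49, both with the block, while sox18.S was the member that fell. Without mixer and sox17b, a choice made after the values were seen, the median was 0.53 (adjusted p = 4.42e-11, adjusted p = 0.119 with an estimated correlation).

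Of 28 mesoderm genes, 0 passed in Mixer caps without the block (2 rose adjusted over the list alone) and 4 rose with it (6 adjusted over the list alone), among them aplnr.L, wnt11b.L, wnt8a.L (1.11) and hes7.1.L (0.77). Their median was 0.12 (camera adjusted p = 0.000246, adjusted p = 0.291 with an estimated correlation). Of 20 organizer genes, 0 passed without the block (1 rose adjusted over the list alone), and with it cer1.S rose and hesx1.L fell by 0.68 (3 and 1 adjusted over the list alone). The organizer median was 0.14 (adjusted p = 0.0101, adjusted p = 0.37 with an estimated correlation), and the call ended without uninjected replicate 1 (0.282) or Mixer replicate 1 (0.227), and without genes of other lists (0.233). Of 24 epidermal genes, 0 passed without the block (2 rose and 5 fell adjusted over the list alone), and 2 rose and 3 fell with it (2 and 12 adjusted over the list alone). The members that rose were itln1.L and msx2.L, and those that fell were the homeobox genes dlx5.L, dlx6.S (-1.34) and msx1.L (-0.73). Their median was -0.51 (adjusted p = 1.28e-06, adjusted p = 0.37 with an estimated correlation). Of 20 ventral and BMP responsive genes, 0 passed without the block (2 rose and 4 fell adjusted over the list alone), and 2 rose and 3 fell with it (2 and 9 adjusted over the list alone). They included msx2.L and ventx3.2.S (1.31), which rose, and bambi.L, msx1.L and rgma.L (-0.66), which fell. Their median was -0.18 (adjusted p = 0.000317, adjusted p = 0.37 with an estimated correlation).

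Of 17 vegetal and germ plasm RNAs, wnt11b.L rose with the block (2 adjusted over the list alone). That list's median was 0.20 with camera adjusted p = 0.0573, and with the block 0.0444 (adjusted p = 0.657 with an estimated correlation). The vegetal call was also made without uninjected replicate 1 (0.033), without Mixer replicate 2 (0.0188), and without Sox17beta replicate 1 or 2 (0.0232 each). The other 10 lists were not called in Mixer caps by camera. With the block their passing members were wnt11b.L and wnt8a.L of 25 Wnt genes (4 rose adjusted over the list alone) and myc.S (1.14) and hesx1.L of 25 neural plate genes (3 rose and 2 fell adjusted over the list alone). Further single members were efnb2.S (0.74) of 30 adhesion genes, ccng1.L (1.46) of 17 stress genes and sox18.S of 17 blood and vascular genes (1, 2 and 0 rose and 0, 1 and 1 fell adjusted over the list alone). No member passed among 21 Nodal and activin genes (smad4.L -0.66, adjusted p with the block 0.06; smad7.L -0.74, 0.0795), 14 FGF genes (fgfr2.L 0.74, 0.113; fgfr4.S -0.49, 0.32) or 14 gut and liver genes (darmin.L 0.60, 0.119; foxf1.L -0.52, 0.224). None passed among 10 loading genes (tbp.S 0.51, 0.289; gapdh.L 0.49, 0.399) or 32 cell cycle genes (cdk2.S -0.55, 0.0986; ccna1.L 0.52, 0.134). With the block, 3 Nodal genes fell and 1 FGF gene rose adjusted over the list alone, and 0 of the gut and liver, loading and cell cycle lists. Median, mean and test differed in sign for the Nodal (0.07, -0.05), Wnt (-0.04, 0.15), loading (-0.04, 0.04) and blood lists (0.04, -0.09).

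Leaving out a Sox17beta array keeps the differences between Mixer and uninjected caps and changes only the estimate of the spread and its degrees of freedom. The Mixer counts fell when single arrays were left out. Without the block they fell from 6 to 0 without uninjected replicate 1 or 2 and to 1 without any of the other 4 arrays. With the block they fell from 203 to 1 without uninjected replicate 1 or 2, to 0 without Mixer replicate 1 or 2 and to 2 without Sox17beta replicate 1 or 2. In simulated data the blocked fit without 1 Mixer array still recovered 97.4% of 2-fold changes, with 21.1% of its calls false. The simulated spreads had been drawn towards a common value beforehand, so this recovery may be overstated.

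Sox17beta against uninjected caps asks the same of Sox17beta. Apart from sox17b.1.S, the largest difference was that of an unnamed probe set, which rose by 5.92 or 60.8-fold (limma adjusted p = 0.0252) and differed by -0.01 in Mixer caps. These were the 3 probe sets called without the block, all 3 higher, while 969 had an unadjusted p under 0.05 where chance gives 775. With the replicate number as a block, 844 were called, 292 higher and 552 lower, of which 430 differed at least 2-fold, 149 higher and 281 lower. The Iroquois homeobox gene irx4.L read 8.40 ± 0.40 (SD, n = 2) against 4.54 ± 0.03, a rise of 3.86 (adjusted p = 0.0506, with the block 0.000695). The T-box gene eomes.L rose from 5.32 ± 0.13 to 8.07 ± 0.20, by 2.75 (0.055, with the block 0.000852). The organizer homeobox gene gsc.S rose from 3.62, a level inside that of the absent controls, by 2.91 (0.0757, with the block 0.000437). Uninjected means below the highest absent controls of the uninjected arrays (5.9 and 5.99) were also those of irx4.L and eomes.L. The same held for gata4.L (5.14), sox17a.S (4.31), gata4.S (4.13), sox17a.L (4.12) and dmrta2.S (4), among others, so their folds are uncertain.

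The further changes in Sox17beta caps passed only with the replicate block. Rises were called for dmrta2.S, a DM-domain transcription factor, by 3.16 (adjusted p = 0.00311), gata4.S by 2.82 (0.000885) and the peroxiredoxin prdx2.L by 2.6 (0.00182). The anterior homeobox gene otx2.L rose by 2.46 (0.00712), the neuronal RNA-binding protein gene elavl4.L by 2.48 (0.0315; 1.4 and 3.56 in replicates 1 and 2), foxa1.S by 2.42 (0.00218), pisd-like.2.L by 2.38 (0.00663) and irf1.L, an interferon regulatory factor, by 2.34 (0.0324). The rise of irf1.L was 3.33 in replicate 1 and 1.35 in replicate 2. A further unnamed probe set was 3.58 higher (0.024; 2.1 in replicate 1 and 5.06 in replicate 2). Among the largest falls were those of epidermal keratins, krt12.5.S at -3.19 (0.0196), krt12.4.S at -3.11 (0.0481) and krt70.L at -3 (0.028), each larger in replicate 2 than in replicate 1 (for krt12.5.S, -4.25 and -2.13). The prostaglandin synthase gene ptgs2.S fell by 3.06 (0.00694), the epidermal homeobox gene dlx3.S by 2.89 (0.00919) and the cement gland gene ag1.L by 2.84 (0.00462). Both copies of szl, a secreted ventral inhibitor of chordin-cleaving proteases, fell, szl.S by 2.84 (0.00572) and szl.L by 2.72 (0.0055). The largest falls of unnamed probe sets were -2.8 (0.00579) and -2.67 (0.0124). Neither copy of sox17a passed, with differences of 0.14 (sox17a.S, 0.682) and 0.16 (sox17a.L, 0.839), nor did gata4.L (0.27, 0.326).

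Of 24 measured epidermal genes, 0 passed in Sox17beta caps without the block (13 fell adjusted over the list alone), and 13 fell and 0 rose with it (15 and 1 adjusted over the list alone). They included dlx3.S, krt12.4.L (-2.29, adjusted p = 0.0181), the epidermal transcription factor tfap2a.L (-2.12, 0.00539) and the GATA factor gata2.L (-1.94, 0.00311). The list's median was -1.33 (camera adjusted p = 4.28e-18, adjusted p = 0.163 with an estimated correlation). Of 20 ventral and BMP responsive genes, 0 passed without the block (12 fell adjusted over the list alone), and 12 fell and 0 rose with it (15 and 1 adjusted over the list alone). They included szl.L, bambi.L (-2.19, 0.00218), gata2.L and the BMP ligand bmp7.2.L (-1.84, 0.0107). Their median was -1.01 (adjusted p = 7.99e-15, adjusted p = 0.152 with an estimated correlation).

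Of 17 endoderm regulators, sox17b.1.S rose in Sox17beta caps without the block (4 rose and 1 fell adjusted over the list alone), and 5 rose and 1 fell with it (5 and 2 adjusted over the list alone). They were sox17b.1.S, eomes.L, foxa1.S, otx2.S (2.33) and gata5.L (0.86), which rose, and sox18.S (-1.38), which fell. The list's median was 0.27 (camera adjusted p = 2.98e-06, adjusted p = 0.152 with an estimated correlation), and without the injected genes adjusted p = 0.000321 (0.163 with an estimated correlation). Of 20 organizer genes, 0 passed without the block (4 rose adjusted over the list alone), and 4 rose and 2 fell with it (4 and 3 adjusted over the list alone). Those that rose were otx2.S, foxa4.S (1.56), the activin and BMP antagonist fst.L (1.43) and the LIM homeobox gene lhx1.L (1.38), and those that fell were sfrp2.S (-1.74) and hesx1.L (-0.69). Their median was 0.26 (adjusted p = 0.000384, adjusted p = 0.163 with an estimated correlation), and the call ended among probe sets above the 25th percentile (0.215). The organizer list holds gsc through gsc.L, which differed by 0.28 (0.327), unlike gsc.S. Of 28 mesoderm genes, 0 passed without the block (1 rose adjusted over the list alone), and with it eomes.L, aplnr.L (1.98) and wnt8a.L (0.69) rose and hes7.1.L (-1.12) fell (7 and 2 adjusted over the list alone). Their median was 0.22 (adjusted p = 0.000384, adjusted p = 0.163 with an estimated correlation), and the call ended without Sox17beta replicate 1 (0.0595).

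Of 32 cell cycle genes, 0 passed in Sox17beta caps without the block (1 fell adjusted over the list alone), and 1 rose and 3 fell with it (1 and 3 adjusted over the list alone). Cyclin genes ccne2.L (-2.41) and ccnd1.S (-1.44) fell with the kinase gene cdk2.S (-0.66), and the cyclin gene ccna1.L (0.81) rose. The median was -0.08 (camera adjusted p = 0.0315, adjusted p = 0.587 with an estimated correlation), and the call ended with quantile normalization (0.37), among probe sets above the 25th percentile (0.119), without genes of other lists (0.0671), without uninjected replicate 1 (0.5) and without Sox17beta replicate 2 (0.478). The other 10 lists were not called in Sox17beta caps by camera. With the block, 1 Wnt gene rose (wnt8a.L) and 5 of 25 fell, among them sfrp2.S, ccnd1.S, fzd8.S (-1.07) and tcf7l1.L (-0.90). Of 21 Nodal and activin genes, tgif2.S (-1.24), tdgf1.3.L (-1.03) and smad7.L (-0.81) fell, and of 14 FGF genes the receptors fgfr4.S (-1.16) and fgfr1.L (-0.64). Adjusted over the list alone, 2 Wnt genes rose and 5 fell, 2 Nodal genes rose and 7 fell, and 1 FGF gene rose and 2 fell. Of 30 adhesion genes, 4 fell with the block (2 rose and 6 fell adjusted over the list alone), namely cxcr4.L (-1.68), rnd1.S (-1.47), the epithelial cadherin cdh1.S (-1.01) and pcdh1.L (-0.76). The other copy of the chemokine receptor gene, cxcr4.S, rose by 1.65 (0.00363). The adhesion list was called with quantile normalization (0.0359; adjusted p = 0.66 with an estimated correlation and no other change).

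Of 25 neural plate genes, otx2.S and foxd3.S (1.5) rose in Sox17beta caps with the block and 3 fell, among them tubb2b.S (-1.11) and hesx1.L (5 rose and 9 fell adjusted over the list alone). Of 17 vegetal and germ plasm RNAs, dnd1.L (1.24) rose and fzd7.L (-0.62) fell (3 and 4 adjusted over the list alone). Of 17 stress genes irf1.L rose and xbp1.L (-2.11) fell (2 and 4 adjusted over the list alone), and of 17 blood and vascular genes gata2.L and sox18.S fell (2 adjusted over the list alone). Of 10 loading genes, tbp.S (1.2) rose (2 adjusted over the list alone), and of 14 gut and liver genes 0 passed (0 adjusted over the list alone), the smallest p being those of shh.L (0.39, adjusted p = 0.0996) and foxf1.L (-0.51, 0.143). The gut and liver list was called as higher without genes of other lists (0.0384; adjusted p = 0.587 with an estimated correlation on the whole list). Median, mean and test differed in sign for the Nodal (0.05, -0.12), Wnt (0.10, -0.09), FGF (0.06, -0.02), adhesion (0.01, -0.11), blood (0.04, -0.14), stress (0.06, -0.02) and loading lists (0.03, 0.13).

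Leaving out a Mixer array likewise keeps the differences between Sox17beta and uninjected caps and changes only the spread estimate and its degrees of freedom. The Sox17beta counts also changed when single arrays were left out. Without the block they went from 3 to 5 without Sox17beta replicate 1, to 1 without Sox17beta replicate 2, and to 0 without either uninjected or either Mixer array. With the block they went from 844 to 582 without Sox17beta replicate 1, to 3 without Sox17beta replicate 2, and to 0 without either uninjected or either Mixer array.

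**Figure D2:**
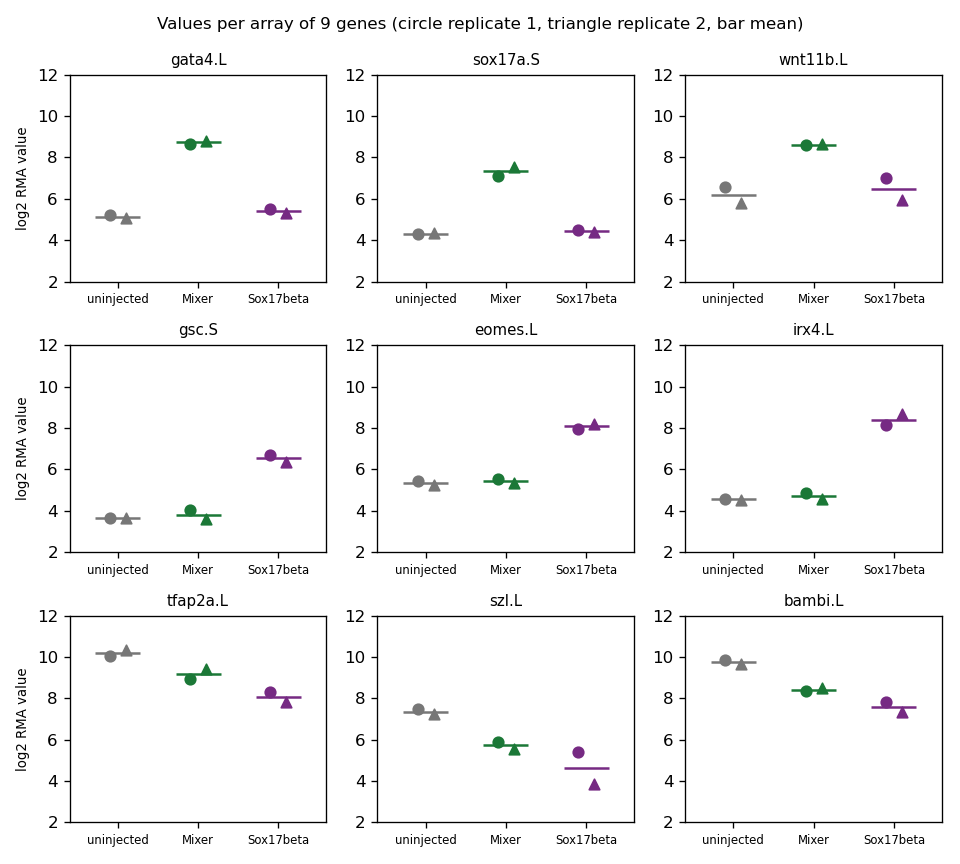
Log2 RMA values of 9 genes on the 6 arrays, with circles for replicate 1, triangles for replicate 2 and bars for group means. In Mixer caps gata4.L averages 8.73 against 5.14 in uninjected and 5.42 in Sox17beta caps, whereas irx4.L averages 8.40 in Sox17beta caps against 4.54 in uninjected and 4.71 in Mixer caps.

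The direct comparison of Mixer with Sox17beta caps tests which differences between the injected groups exceed their spread. In Mixer caps mixer.L was 7.38 higher (limma adjusted p = 0.00105), gata4.L 3.32 higher (0.0173) and sox17a.S 2.89 higher (0.04) than in Sox17beta caps. In Sox17beta caps irx4.L and eomes.L were higher, with differences of Mixer minus Sox17beta of -3.69 and -2.63 (both 0.04), as were the shared probe set of sox17b.1.S (-3.48, 0.04) and the unnamed probe set that Sox17beta raised 60.8-fold (-5.94, 0.0185). The pair of unnamed probe sets that rose with Mixer were higher in Mixer caps, by 3.98 (_x_at, 0.0112) and 3.79 (_at, 0.0185). These 9 were the probe sets called without the block, 5 higher and 4 lower in Mixer caps. With the block 241 were called, 155 higher and 86 lower.

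With the block, itln1.L was higher in Mixer than in Sox17beta caps by 3.60 (adjusted p = 0.00561), the kinase gene sgk1.L by 3.12 (0.00539), sox17a.L by 3.01 (0.00863), msx2.L by 2.88 (0.000471) and plekhn1.L by 2.81 (0.0108). Lower in Mixer caps were the gene-specific probe set of sox17b.1.S (-4.03, 0.00121), the crystallin gene crygbl.4.S (-3.18, 0.000471), gsc.S (-2.73, 0.000471), dmrta2.S (-2.70, 0.00795), otx2.S (-2.16, 0.0293; -1.45 and -2.87 in replicates 1 and 2), the amino acid transporter slc7a8.S (-1.93, 0.00323) and a further unnamed probe set (-2.86, 0.0051). The copies of gata4 differed in this test, gata4.S being 0.91 higher in Mixer caps (0.0473) and gata4.L 3.32 higher.

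Of 20 ventral and BMP responsive genes, 0 passed between the injected groups without the block (9 higher in Mixer caps adjusted over the list alone), and 7 were higher and 0 lower with it (13 and 1 adjusted over the list alone). They included msx2.L, ventx3.2.S (1.85), ventx2.1.S (1.32) and gata2.L (1.31). The list's median was 0.82 (camera adjusted p = 3.05e-11, adjusted p = 0.403 with an estimated correlation). Of 24 epidermal genes, 0 passed without the block (7 higher adjusted over the list alone), and itln1.L, msx2.L, gata2.L and msx1.L (0.92) were higher with it (11 adjusted over the list alone). Their median was 0.79 (adjusted p = 6.56e-13, adjusted p = 0.403 with an estimated correlation). Of 32 cell cycle genes, 0 passed without the block (1 higher adjusted over the list alone), and ccne2.L (1.71) and ccnd1.S (1.06) were higher with it (5 adjusted over the list alone). Their median was 0.13 (adjusted p = 0.00686, adjusted p = 0.622 with an estimated correlation), and the call ended with quantile normalization (0.0604), without Mixer replicate 1 (0.216) and without Sox17beta replicate 2 (0.385).

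The other 13 lists were not called by camera between the injected groups (adjusted p from 0.594 to 0.76 with an estimated correlation). Of 17 endoderm regulators, 3 were higher and 1 lower in Mixer caps without the block (4 and 4 adjusted over the list alone), and 4 were higher and 3 lower with it (5 and 4 adjusted over the list alone). Those higher were mixer.L, gata4.L, sox17a.S and cer1.S (1.18), and those lower sox17b.1.S, eomes.L and otx2.S. The endoderm median was 0.17 (camera adjusted p = 0.0887). Without Mixer replicate 1 the median was -0.04, yet the list was called, as higher in Mixer caps. The list holds the injected genes themselves. Without genes of other lists the endoderm median was 0.56 (0.00122). Of 20 organizer genes, 3 were higher, among them sfrp2.S (1.90) and not.L (1.80), and 4 lower with the block, among them otx2.S and foxa4.S (-1.54), with 4 and 4 adjusted over the list alone. The organizer median was -0.07 (0.218), and the list was called as lower without Sox17beta replicate 2 (0.016) and without genes of other lists (0.00123). Of 28 mesoderm genes, eomes.L was lower without the block (1 adjusted over the list alone), and with it wnt11b.L (2.15) and hes7.1.L (1.90) were higher as well (4 higher and 1 lower adjusted over the list alone).

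Of 25 Wnt genes, wnt11b.L, sfrp2.S and ccnd1.S were higher in Mixer than in Sox17beta caps with the block (7 adjusted over the list alone), with a median of 0.02 and camera adjusted p = 0.0649 (adjusted p = 0.729 with an estimated correlation). That list was called with quantile normalization (0.0442), among probe sets above the 25th percentile (0.018), and without either uninjected array (0.0497 each), Mixer replicate 2 (0.0326) or Sox17beta replicate 1 (0.00258). Adhesion genes higher with the block were cxcr4.L (1.49), rnd1.S (1.32) and efnb2.S (1.26) of 30 (3 higher and 1 lower adjusted over the list alone). Of 17 stress genes they were xbp1.L (1.82) and ccng1.L (1.37) (4 and 1 adjusted over the list alone), a list called without Mixer replicate 1 (0.0442). Of 25 neural plate genes, myc.S (1.62) was higher and otx2.S and foxd3.S (-1.42) lower (4 and 2 adjusted over the list alone). Single members higher were tgif1.S (0.74) of 21 Nodal genes, fgfr2.L (1.15) of 14 FGF genes, wnt11b.L of 17 vegetal RNAs and gata2.L of 17 blood genes (3, 3, 3 and 1 higher and 1, 0, 0 and 0 lower adjusted over the list alone). The vegetal list was called without Mixer replicate 2 (0.024), and the FGF list without genes of other lists (0.0418). No member passed among gut and liver genes (shh.L -0.36, adjusted p = 0.19; darmin.L 0.41, 0.264) or loading genes (tbp.S -0.69, 0.13; slc35b1 -0.30, 0.297). Median, mean and test differed in sign for the Nodal (-0.04, 0.07), FGF (-0.04, 0.11), mesoderm (-0.02, 0.04) and blood lists (-0.07, 0.05). The uninjected arrays are outside this comparison, so their omission changes only the spread estimate and its degrees of freedom. Counts without the block fell from 9 to 1 when any of the 6 arrays was left out. With the block they fell from 241 to 12 without either uninjected array, to 0 without either Mixer array, to 136 without Sox17beta replicate 1 and to 1 without Sox17beta replicate 2.

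Several genes moved the same way in both injected groups. In the blocked fit, gata4.S (3.72 in Mixer and 2.82 in Sox17beta caps), aplnr.L (2.73 and 1.98), foxa1.S (1.68 and 2.42), cxcr4.S (1.51 and 1.65) and prdx2.L (1.35 and 2.6) rose in both, as did sox17b.1.S. The oocyte genes btg4.L (1.07 and 1.52) and fbxo43.L (0.98 and 1.21) completed the 8 shared rises taken by the rule for named genes. That rule ranks genes by the smaller of their differences and reads each gene at its brightest probe set where groups do not overlap, so some larger shared changes, such as that of a dimmer probe set of otx2.L (2.06 and 3.13), are not among them. The 8 shared falls taken by the same rule were those of slc2a2.L (-1.59 and -2.48), slc38a2.L (-1.58 and -1.75), asl.L (-1.55 and -1.93), dlx5.L (-1.49 and -1.66), kctd15.L (-2.28 and -1.46, the latter -0.76 in replicate 1 and -2.15 in replicate 2), sox18.S (-1.46 and -1.38), bambi.L (-1.35 and -2.19) and tuba1cl.3.L (-1.31 and -1.53).

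Without the block the groups shared 1 called probe set, the _s_at probe set of sox17b.1.S, against 0 in each of 100 simulations of unchanged groups with the same controls. Independent lists would share 0.00116. With the block, 26 probe sets were higher in both groups, where simulations averaged 0.05 with a maximum of 1 and independent lists would share 1.56. Lower in both were 106, where simulations averaged 0.19 with a maximum of 2 and independent lists would share 4.28, and 3 were called in opposite directions. The unchanged simulated groups call few probe sets, so a large overlap could not arise there. With the block they averaged 0.92 (Mixer) and 0.91 (Sox17beta) higher calls, and 1.02 and 1.08 lower ones. The simulated overlaps therefore do not measure what shared controls add to lists of the observed size. Across probe sets, which are not independent replicates, the log2 differences of both groups correlated at 0.574, against 0.501 on average and at most 0.525 in the simulations. Their covariance was 0.0661 against 0.00944, a difference of 0.0567. The signs were the same for 67.0% of probe sets and for 66.7% in the simulations. Part of the overlap beyond independent lists may come from the shared controls, whose 2 arrays are too few to give each group its own pair. Mixer differences of replicate 1 and Sox17beta differences of replicate 2, which share no array, correlated at 0.435 with a covariance of 0.069, and the reverse pairing at 0.378 with 0.0443. The correlation of 0.574 moved to 0.756 without uninjected replicate 1, to 0.354 without Mixer replicate 1 and to 0.376 without Sox17beta replicate 1. The overlap without the block fell to 0 when any array was left out. With the block, the 132 probe sets changed in the same direction fell to 1 without either Sox17beta array and to 0 without any of the other 4 arrays.

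**Figure D3:**
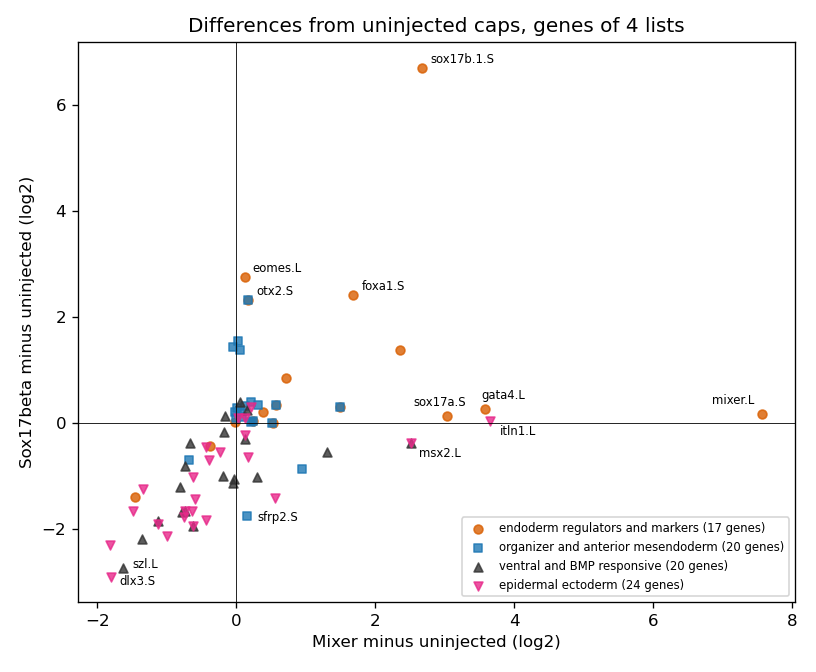
Log2 difference from uninjected caps in Mixer caps (horizontal) and Sox17beta caps (vertical) for the measured genes of 4 lists, 1 point per gene and list. Epidermal genes (median -0.51 in Mixer and -1.33 in Sox17beta caps) and ventral genes (-0.18 and -1.01) lie mostly below 0 on the vertical axis, while sox17a.S (3.03 and 0.14) and eomes.L (0.12 and 2.75) lie near opposite axes.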

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

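Chosen only after the result was seen were the tests of quantile scaling, of carried-over RNA, of RNA degradation and of developmental lists against the replicate number. A few genes moved in opposite directions in the injected groups, each passing with the replicate block in both groups and in the direct test. The Hes-family gene hes7.1.L differed from uninjected caps by 0.77 with Mixer and by -1.12 with Sox17beta, a direct difference of 1.90 (adjusted p = 0.000575 with the block). The transporter gene slc7a8.S differed by -1.25 and 0.69, a direct difference of -1.93 (0.00323). An unnamed probe set, the _x_at one of the pair that rose with Mixer, differed by 3.06 and -0.92, a direct difference of 3.98 (6.56e-05).

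With the block, Sox17beta changed 844 probe sets and Mixer 203. Uneven scaling left in the deposited values would bring these counts together after quantile normalization, but their ratio was then still 3.3, which argues against it. RMA had already brought the arrays to a common distribution, so the test covers only what was left. A single deviant array, Sox17beta replicate 2, stays open, because within replicate 1 the numbers of probe sets at least 2-fold from uninjected were 336 and 224, a ratio of 1.5, and within replicate 2 they were 747 and 280. Leaving out Sox17beta replicate 2 gave 3 calls, and leaving out replicate 1 gave 582. Sox17beta replicate 1 stood out as well. It had the highest maximum of the absent controls (6.62, others 5.9 to 6.09) and the lowest SD of its values (1.817, others 1.874 to 1.923). Which Sox17beta array deviates, if either, was therefore not settled. A stronger action of Sox17beta or a higher dose of its RNA may also account for the difference in counts and was not tested.

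Both probe sets of sox17b rose in Mixer caps, by 2.67 and 4.14. Carry-over of RNA from Sox17beta caps, which would raise every probe set that Sox17beta raised in proportion, would need shares in replicates 1 and 2 of 10.2% and 7.02% for the shared probe set and of 7.71% and 3.55% for the gene-specific one. Of 34 probe sets raised over 4-fold by Sox17beta, 2 lay below the prediction from the gene-specific probe set past an adjusted p of 0.05. They were the unnamed one that Sox17beta raised 60.8-fold (observed minus predicted -2.07 ± 0.29 SE, adjusted p = 0.00245) and one of crygbl.4.S (-1.16 ± 0.177, 0.00293). Below the prediction from the shared one lay 3, with irx4.L added (-0.93 ± 0.242, 0.025). The crygbl.4.S probe set counts for little, since its predicted rise was 0.29 and it differed by -0.88 in Mixer caps. From the gene-specific share, irx4.L did not pass (-0.606, 0.0924), and another unnamed probe set lay at its prediction (0.00403). The prediction takes values to be proportional to RNA. The gene-specific sox17b probe set read 13.9 in Sox17beta replicate 2, the highest value of that array, so its share may be overstated there. The 60.8-fold probe set and irx4.L averaged 4.92 and 4.54 in uninjected caps, inside the range of the absent controls, where rises can be understated. Only if proportional do the values argue against carry-over as the whole rise of either sox17b probe set, for the gene-specific one through the 60.8-fold probe set alone. The criterion of an adjusted p of 0.05 was set after values were seen and replaced others. The median of observed minus predicted (0.138 from the gene-specific probe set) would have spoken for carry-over there. A count beyond 3 standard errors in both replicates (2 and 4, where 3 or more were required) would have left it open there. A smaller share of carried-over RNA beside another cause, induction of the embryo's own sox17b by Mixer, as for sox17a, contact with injected Sox17beta RNA alone and cross-hybridization may each account for the rise and were not tested.

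Replicate numbers separated the arrays more than the injections did. A smooth trend on intensity, as hybridization or scanning would give, took at most 2.41% of the variance between replicates. The same-number correlations were 0.872, 0.749 and 0.779 after its removal. RMA brings arrays to a common distribution and so removes most of such a trend beforehand. These values therefore cannot decide whether hybridization or scanning gave the pattern. For RNA degradation, the 3-prime minus 5-prime difference of the Gapd and beta-actin control transcripts shifted by at most 0.22 between numbers. The 3-prime beta-actin probe set read 5.56 to 6.33, near the highest absent controls (5.9 to 6.62), so it could hardly follow degradation. The Gapd difference was 0.76 and 0.67 (uninjected), 0.79 and 0.79 (Mixer) and 0.66 and 0.83 (Sox17beta) in replicates 1 and 2. This argues against degradation for that transcript only. Different embryos or a small difference in stage may account for the pattern and stay open, as the smallest adjusted p of any of the 16 lists between replicate numbers was 0.341 and a number holds embryos and hybridization together. The hybridization controls also differed between numbers, by 1.23 to 1.67.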

How the results depend on the processing

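The alternatives that combine the replicate block with another setting, and the endoderm list without the injected genes, were chosen only after seeing the data; all others were chosen beforehand. No injected or named gene changed direction under any alternative, but the majority direction of some counts did. Among lists, the test's direction held wherever both were called, but the median of endoderm regulators between injected groups went from 0.17 to -0.04 without Mixer replicate 1, and that of cell cycle genes with Sox17beta from -0.08 to 0.05 without Sox17beta replicate 2. Of 82 values of named genes, 12 were called without the block. All 12 calls were lost without either uninjected or either Mixer array, without Sox17beta replicate 2, with only the 4 arrays compared and at an adjusted p under 0.01, and 11 without Sox17beta replicate 1. The other 70 were all called with the block. Over lists and comparisons, the 14 calls were lost in 40 of 202 values under the alternatives, and the 34 lists not called became called in 24 of 479. An alternative for linear values was not run because the values are log2. Limits come from the number of arrays and from dim probe sets, since 48.5% to 60.7% of probe sets per array lay above that array's highest absent control. Fits without an array leave 1 group with a lone array, assumed to vary like the others. Except where stated, the cause of a change was not tested.

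Without the block, the calls were 6 (Mixer), 3 (Sox17beta) and 9 (Mixer against Sox17beta), with 1 shared. With the replicate block they were 203 (83 higher, 120 lower), 844 (292 and 552) and 241 (155 and 86), where without it all 6 and all 3 were higher, with 132 shared, since the block removes the variation between replicate numbers from the residual. The block also called mixer.S (0.78) and the gene-specific probe set of sox17b.1.S (2.67) in Mixer caps, the latter also between injected groups (-4.03, adjusted p = 0.0566 without the block and 0.00121 with it), and the vegetal list in Mixer caps (0.0444). It changed no other call of an injected gene or, by camera, of a list. Quantile normalization gave 5 for Sox17beta and, between injected groups, 5 higher and 6 lower in place of 5 and 4. Above the median intensity there were 3 for Mixer and 3 between injected groups. With eBayes trend there were 13 (8 higher, 5 lower) for Sox17beta and 14 (7 and 7) between injected groups. With only the 4 arrays compared there were 1, 0 and 1, with 0 shared, and the calls of sox17b.1.S were lost at 4.14 (Mixer, adjusted p = 0.0753), 6.7 (0.11) and 7.62 (0.0569). At an adjusted p under 0.01 there were 1, 1 and 1, with 0 shared, and the calls at 4.14 and 6.7 were lost. With 1 probe set per gene there were 3 (Mixer) and 1 (Sox17beta), with 0 shared, as fewer probe sets were tested.

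Leaving out 1 array gave 0 to 1 (Mixer), 0 to 5 (Sox17beta), 1 to 1 (Mixer against Sox17beta) and 0 to 0 shared. The correlation of differences ranged from 0.354 to 0.756. In Mixer caps mixer.L ranged from 7.53 to 7.61, mixer.S from 0.58 to 0.97, and the gene-specific and shared probe sets of sox17b.1.S from 2.52 to 2.83 and from 4.07 to 4.2. In Sox17beta caps the latter pair ranged from 6.3 to 7.1 and from 7.31 to 7.93. With the replicate block, leaving out 1 array gave 0 to 2 (Mixer), 0 to 582 (Sox17beta), 0 to 136 (between injected groups) and 0 to 1 shared. For the Mixer count without a Mixer array, simulated data without 1 Mixer array still gave back 97.4% of 2-fold changes, with 21.1% of calls false. The simulated spreads had already been drawn towards a common value by the full blocked fit. Of the 203 real calls with the block, 110 differed at least 2-fold, whereas all simulated changes did. The simulation therefore cannot tell whether the loss of an array alone accounts for the fall. The Sox17beta counts, those between injected groups and the shared ones were not simulated.

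Combined with the replicate block, counts in the order Mixer, Sox17beta, between injected groups and shared were as follows. Above the median intensity they were 81, 502, 93 and 58. With only the 4 arrays compared they were 2, 0, 12 and 0. With at least a 2-fold difference they were 110 (60 higher, 50 lower), 430, 165 and 54. At an adjusted p under 0.01 they were 22 (18 and 4), 296, 71 and 8. With 1 probe set per gene they were 117, 438, 148 and 69. Other settings with the block (centring, quantile normalization, the 25th percentile, trend, robust) stayed within 1.5 times. Without the block, fry called the endoderm list alone, for Mixer (0.00191) and Sox17beta (0.0153), and an estimated correlation the endoderm list for Mixer alone (0.0381). That list holds the injected genes mixer and sox17b, whose rise comes with the injection. Without them the call with an estimated correlation was lost, and fry was not run without them. With the block, fry called the endoderm and mesoderm lists for Mixer (0.0378 each) and not the endoderm list for Sox17beta (0.0747), and an estimated correlation did not call the endoderm list for Mixer (0.378). The vegetal list was called for Mixer with the mean of all probe sets (0.0359), quantile normalization (0.0447), the 25th percentile filter (0.0117) and without genes of other lists (0.042).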

Other observations

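The tests named here were planned before their results were seen, but the genes were chosen after their values were seen. Gene copies and probe sets did not always move together. The dimmer probe set of otx2.L rose in Mixer caps by 2.06 (limma adjusted p = 0.0248 with the replicate block), whereas otx2.S differed by 0.17 (0.91), and in Sox17beta caps they rose by 3.13 and 2.33. For gsc in Sox17beta caps, gsc.S rose by 2.91 and the dimmer probe set of gsc.L by 0.84 (0.028), while the brighter gsc.L probe set differed by 0.28. Both probe sets of crygbl.4.S, a lens crystallin gene, were higher in Sox17beta caps, by 3.88 and 2.31, and differed by -0.09 and -0.88 in Mixer caps. The unnamed probe set that rose by 5.92 in Sox17beta caps shares the stem of its identifier with a probe set named hbg1.L, a globin gene, which differed by 0.18 (0.485). Of 148 list genes with several probe sets, 0 had probe sets called in opposite directions in Mixer caps and 1, cxcr4, in Sox17beta caps.

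A hypothesis was tested that injected caps keep more maternal oocyte RNA, because btg4.L and fbxo43.L, genes of the oocyte, rose in both groups, and btg4.S differed by 1.22 (Mixer) and 2.06 (Sox17beta). A list of 37 other maternal genes, 11 of them also in the 16 lists, had a median difference of 0.09 in Mixer caps (camera adjusted p = 0.0412 with the block, 0.274 without; p = 0.114 with the block and an estimated correlation) and of 0.05 in Sox17beta caps (0.556 with the block). With the block 0 of them rose in either group, and 0 (Mixer) and 1 (Sox17beta) fell. The medians lie below 0.2, and the Mixer list passed only with the block and the preset correlation, so the hypothesis is neither shown nor excluded.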
